A study of Mus musculus with 15 samples.

How the data were processed

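RNA was sequenced from CD45-negative, CD31-positive cells sorted by flow cytometry from the hearts of 15 mice, 3 WT sham, 5 WT TAC, 3 KO sham and 4 KO TAC, 4 weeks after surgery. Per the labels' protocols RNA was extracted with an RNeasy Plus kit and libraries were made with a TruSeq kit. Per the submitters' processing notes reads were aligned with HISAT2 2.1.0 to the mouse genome build mm10. The authors deposited 1 table of counts, in which each value is the number of reads assigned to the exons of a gene in a library. Per the file headers these counts came from featureCounts 1.6.2 with strand setting 2 and the UCSC gene annotation of mm10, with no option for multimapping reads or for reads that overlap several genes, so such reads were not counted. A gene with a near-identical copy is therefore undercounted, which may apply to histocompatibility and small RNA genes. The loss was not measured. Because the counting used strand, reads from antisense genes were told apart. Coordinates are those of the table, on mm10, and are 1-based.

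The table held 23337 genes, of which 6512 had no count in any library. Some symbols in the table had been turned into dates by spreadsheet software, and 18 such entries were among the genes tested without being named here. Each of the 15 columns matched 1 sample by its mouse number and surgery, and 0 columns were left over. Groups were taken from the genotype and treatment given for each sample. The labels name 1 batch for all libraries and give no sex, and WT and KO mice have different mouse numbers that pair no samples. Genes carry the older symbols of the annotation, with current names in brackets where they differ.

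Total counts ran from 1362346 to 15670319 per library, and the 10 most abundant genes took 13.1% to 18.7% of them. Where a gene was at 0, a floor of 3 counts was used. Such a floor covers counting error at most, since reads without molecular identifiers are not independent molecules. The SD of levels and the SE of log2 fold changes reflect the spread between libraries. Levels are CPM, counts scaled to a common library total, computed from the deposited counts with TMM-scaled library sizes, whose factors lay between 0.9599 and 1.031.

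Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (a minimum count of 10, scaled by depth, and a total of 15), which left 12471. Libraries were scaled by TMM, and 1 model with a coefficient per group was fitted to all 15 libraries by glmQLFit, with 11 residual degrees of freedom. Contrasts were tested with glmQLFTest, two-sided, and p-values were adjusted by Benjamini-Hochberg within each of 5 comparisons, with a threshold of 0.05. The comparisons were TAC against sham in each genotype, KO against WT after each surgery, and the difference between the 2 TAC effects. Separate mice were used throughout, and the p-values of these contrasts measure the spread between these mice. Every gene said to rise, fall or change passed this test, also where no p is printed beside it.

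Gene lists for pathways and for cell types of the heart were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 788 list entries 749 matched the table by symbol, 18 through synonyms in a RefSeq table and 21 not at all. Of 37 lists 29 had at least 5 genes tested and were tested with camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 29 lists. Camera compares a list with all other genes. An inter-gene correlation estimated per list was used beside it, and fry, which tests whether a list's genes move on balance one way. In WT TAC against WT sham the calls on extracellular matrix, venous and angiogenesis genes held with an estimated correlation, and in the other 4 comparisons none did. Some tested genes are not reported here.

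The rule for named genes took, in each pairwise comparison, the 10 higher and 10 lower genes with the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM over both groups, no overlap between the groups' libraries and a named symbol, and for the difference of the TAC effects the 10 with the smallest p. It also took up to 4 members of each list with the smallest p and a list of genes of the STING pathway and of endothelial activation. Of these the text names those needed to describe each comparison, preferring genes whose call did not depend on a single library. Cdkn1b, Fas, Sesn1, Igfbp7, Cyr61, Xaf1, Ifi27l2a, Eif2ak2 and Wt1 lie outside the rule in a comparison where they are named and were chosen after their values were seen.

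The alternatives were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no low-count filter, a filter of 5 CPM in 3 libraries, a fit with only the groups compared, limma voom with sample quality weights, the mean log2 CPM of the cardiomyocyte list as a covariate, a test against a fold of 1.5, and each library left out in turn. A fit without WT sham 133, KO sham 348 and KO sham 350, the libraries apart in depth or in genes at 0, was added after the data were seen. It leaves 1 KO sham library, so the other groups supply its spread and its calls on KO sham are no test. A sex covariate had been planned and was not fitted, because Y-linked genes were expressed in all 15 libraries. With RLE factors and DESeq2 size factors the share of higher genes among those called moved by less than 10 percentage points in each comparison.

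The same steps were tested on simulated counts for the 12471 genes with 200 genes changed. Among called genes 6.71%, 3.38%, 4.08%, 7.59% and 5.31% were false in the 5 comparisons, in the order WT TAC against WT sham, KO TAC against KO sham, KO TAC against WT TAC, KO sham against WT sham and the difference of the TAC effects. Of genes changed 2-fold 74.6%, 65.7%, 67.2%, 73.1% and 64.2% were recovered, and of genes changed 4-fold 90.9%, 95.5%, 97%, 83.3% and 83.3%. The simulated genes varied independently, and no simulated library had the excess of genes at 0 seen in KO sham 348 and 350. The rates therefore need not hold for the real calls.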

Results

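RNA was sequenced from endothelial cells sorted from mouse hearts as cells positive for the endothelial surface protein CD31 and negative for the leukocyte protein CD45. The mice carried loxP-flanked alleles of the gene for STING, an adaptor of the innate immune response to cytosolic DNA, either with a Cad5-CreERT2 recombinase that acts in endothelium (KO) or without it (WT). Hearts were taken 4 weeks after transverse aortic constriction (TAC), a surgery that narrows the aorta and puts the left ventricle under pressure overload, or after sham surgery. The 15 libraries formed 4 groups, with 3 WT sham, 5 WT TAC, 3 KO sham and 4 KO TAC mice. Total gene counts were 11051491, 13742798 and 1362346 in WT sham 131, 132 and 133, and 15670319, 15183074, 13361923, 10956044 and 7344720 in WT TAC 134 to 138. The KO sham libraries 348, 349 and 350 held 8855707, 9608355 and 4801095 counts, and the KO TAC libraries 351 to 354 held 12200965, 10406066, 9772060 and 7134892. Between 11698 and 14576 genes had at least 1 count in a library, and a floor of 3 counts corresponded to 0.191 to 2.2 CPM, which are counts scaled to a common library total. Levels are given as mean CPM ± SD over the libraries of a group, and log2 fold changes as estimate ± SE.

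Libraries of a group had Spearman correlations of 0.953 to 0.994 with each other, and the closest replicate pair still differed by more than sampling noise (chi-square per degree of freedom 3.08). Genes at 0 where at least 10 counts were expected from the other libraries numbered 206 in KO sham 348 and 319 in KO sham 350, against 3 to 28 in the other 13 libraries. The first principal component of log2 CPM held 28.0% of the variance and set KO sham 350 apart at 115.3. The second, with 24.3%, separated the genotypes, with WT libraries at 11.93 to 51.1 and KO libraries at -43.81 to -11.98. The third, with 13.3%, set KO sham 348 apart at -77.14. The Y-linked gene Ddx3y was expressed in all 15 libraries at 59.43 to 131.5 CPM. The X-linked gene Xist was at 4.36 CPM (39 counts) in KO sham 348 and 1.65 CPM (8 counts) in KO sham 350. It was at 0 to 0.818 CPM in the other 13 libraries. The source of the Xist reads was not tested.

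The targeted gene, listed as Tmem173 (Sting1; mm10 chromosome 18, 35733678 to 35740554, minus strand, counted over its exons), was lower in every KO library than in every WT library. Its level was 53.9, 65.6 and 56.4 CPM in WT sham 131, 132 and 133, and 75.6, 73.8, 71.8, 82 and 70.4 CPM in WT TAC 134 to 138. The KO sham libraries 348, 349 and 350 held 22.9, 31.4 and 17.3 CPM, and the KO TAC libraries 351 to 354 held 30.4, 28.1, 19.6 and 29.2 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change of KO against WT was -1.48 ± 0.14 after TAC (adjusted p = 5.78e-08) and -1.28 ± 0.17 after sham (adjusted p = 6.99e-05). TAC itself gave 0.34 ± 0.15 in WT (adjusted p = 0.263) and 0.14 ± 0.16 in KO (adjusted p = 0.635) in the same edgeR test. The counts cover the whole gene, so reads from exons outside the deleted part are included.

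The first comparison, WT TAC against WT sham, asked how cardiac endothelial cells of mice without Cre differed 4 weeks after pressure overload. After TAC 20 of 44 matrix genes were higher and 1 lower, and 9 of 16 fibroblast markers and 3 of 12 venous genes were higher, while Edn1, which encodes the vasoconstrictor precursor preproendothelin, and Cyp1a1, a target of the aryl hydrocarbon receptor, were lower. Col15a1 (chromosome 4, 47208012 to 47313165), a basement membrane collagen, rose from 242 ± 18.8 to 779 ± 79.9 CPM, a log2 fold change of 1.68 ± 0.20 (n = 3 and 5, adjusted p = 5.28e-05 by edgeR's quasi-likelihood test). Edn1 (chromosome 13, 42301270 to 42307989) fell from 28.7 ± 6.93 to 11.5 ± 1.39 CPM, a log2 fold change of -1.38 ± 0.17 (adjusted p = 0.000123, edgeR). Cyp1a1 (chromosome 9, 57687928 to 57703824) fell from 39.4 ± 7.45 to 10.0 ± 4.62 CPM. Of 48 interferon-stimulated genes 0 passed in edgeR, 8 had an unadjusted p under 0.05, and DESeq2 called 1 and limma voom 2.

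Of 44 extracellular matrix genes tested in WT TAC against WT sham, 20 rose and 1, Cyr61 (Ccn1), fell, with a median log2 fold change of 0.69. Adjusted over the list alone, 35 rose and 1 fell. The list was called higher (camera adjusted p = 2.1e-27, and adjusted p = 0.022 with an estimated correlation). Among its members Cilp, a cartilage matrix protein that is also made by cardiac fibroblasts, rose by 4.41 ± 0.54, Postn (periostin) by 2.64 ± 0.40, Ctgf (Ccn2) by 1.08 ± 0.16 and Col4a1, a collagen of the endothelial basement membrane, by 0.59 ± 0.09. The level of Col4a1 was 4090 ± 207 CPM after sham and 6150 ± 428 CPM after TAC. Cyr61 lost its call without WT sham 132 or 133 or WT TAC 134 or 137 (adjusted p = 0.104, 0.236, 0.0895 and 0.0961 by edgeR). Of 16 fibroblast markers 9 rose and none fell, 11 and 0 adjusted over the list alone. The median was 1.39 (camera adjusted p = 4.2e-11, and adjusted p = 0.091 with an estimated correlation). Mfap5, a microfibril protein, rose by 2.38 ± 0.41 and Pi16, a marker of adventitial fibroblasts, by 1.17 ± 0.17. The 18 fibroblast genes in the file summed to 371.9 ± 106 CPM in WT sham and 769.5 ± 102 CPM in WT TAC.

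Venous endothelial genes were called higher in WT TAC, with 3 of 12 higher and none lower, 7 and 0 adjusted over the list alone, and a median of 0.35 (camera adjusted p = 9.9e-06, and adjusted p = 0.022 with an estimated correlation). Lrg1, a secreted glycoprotein of post-capillary venules, rose from 0.971 ± 0.376 to 7.29 ± 1.8 CPM. Angiogenesis and tip cell genes were also called higher (4 of 36 higher, none lower, 6 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00032, and adjusted p = 0.029 with an estimated correlation). Trp53i11 rose by 0.90 ± 0.09, from 326 ± 19.4 to 611 ± 33.6 CPM. Vasoactive and flow-responsive genes, 4 of 27 higher and 1 lower (6 and 1 adjusted over the list alone), had a camera adjusted p of 0.0028, and adjusted p = 0.1 with an estimated correlation. In that group Ednrb, the endothelin receptor of endothelium, rose by 1.32 ± 0.14 to 422 ± 45.5 CPM, Ptgs1 (cyclooxygenase 1) by 1.03 ± 0.15 and the potassium channel gene Kcnj2 by 1.47 ± 0.23, while Edn1 fell. Leukocyte adhesion genes (2 of 18 higher, 1 lower, 5 and 1 adjusted over the list alone, median 0.16) had a camera adjusted p of 0.0003, and adjusted p = 0.22 with an estimated correlation; Cd34 rose by 0.76 ± 0.10.

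Immediate early genes, which also respond to tissue dissociation, were called lower in WT TAC (0 of 23 higher, 1 lower, 1 and 5 adjusted over the list alone, median -0.27, camera adjusted p = 0.00082, and adjusted p = 0.67 with an estimated correlation). Fosb fell from 314 ± 62.5 to 127 ± 62.6 CPM, and the call on the list was lost without WT sham 133 (adjusted p = 0.421). The nuclear long noncoding RNA Neat1 fell from 668 ± 83.9 to 332 ± 110 CPM and Kcnq1ot1, the antisense RNA of an imprinted locus, from 318 ± 23.7 to 154 ± 66.1 CPM. Among the genes with the largest increases, Acta1 (skeletal alpha-actin) rose from 0.231 ± 0.236 to 19.7 ± 8.04 CPM, Ankrd1 from 0.543 ± 0.52 to 9.45 ± 4.25 CPM and Xirp2 from 3.39 ± 1.64 to 19.8 ± 4.54 CPM. The cardiomyocyte list as a whole was not called (2 of 21 higher, 1 lower; median 0.02, mean 0.25, camera direction lower with adjusted p = 0.58), and its 24 genes summed to 695.8 ± 19.8 CPM after sham and 637 ± 33.2 CPM after TAC. The higher members of that list included Myh7, whose call was lost without WT sham 131, 132 or 133 (adjusted p = 0.124, 0.116 and 0.0543 by edgeR). Which cells the RNA of Acta1, Ankrd1, Xirp2 and Myh7 came from was not tested. Inhbb, a subunit of activin and inhibin, rose by 2.25 ± 0.29, Tnfaip2 by 1.91 ± 0.27, and the chemokine gene Cxcl12 fell by 0.49 ± 0.08 from 3690 ± 545 CPM. Among interferon genes Isg15 had a log2 fold change of -0.11 ± 0.17, Ifit1 -0.13 ± 0.14, Ifit3 0.04 ± 0.15 and Irf7 0.40 ± 0.14, with adjusted p of 0.844, 0.76, 0.952 and 0.13 in edgeR. The interferon-stimulated list had a camera adjusted p of 0.19 and a median of 0.04, and of 16 genes of the cGAS-STING pathway 0 passed in edgeR (2 higher and 1 lower adjusted over the list alone), 4 had an unadjusted p under 0.05, and DESeq2 called 0 and limma voom 3.

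Camera called 9 of 29 lists in WT TAC against WT sham, 8 higher and 1 lower, of which 3 held with an estimated correlation, and fry called 6. The endothelial identity list (median 0.13, adjusted p = 0.037, and adjusted p = 0.67 with an estimated correlation) lost its call without WT sham 131 or 133, WT TAC 136 or 138, or KO sham 348 or 350 (adjusted p = 0.0972, 0.0977, 0.0921, 0.0895, 0.0577 and 0.0537). MHC class I genes (median 0.12, adjusted p = 0.049, and adjusted p = 0.83 with an estimated correlation) lost theirs with RLE scaling (adjusted p = 0.0546) and in the 9 refits without WT sham 131 or 133, WT TAC 134 or 138, KO sham 348, 349 or 350, or KO TAC 352 or 353 (adjusted p = 0.322, 0.0977, 0.135, 0.171, 0.0577, 0.0681, 0.0565, 0.0571 and 0.0517). In all, 323 of 12471 genes tested changed in WT TAC against WT sham at an adjusted p of 0.05, 200 higher and 123 lower, and 75 of them by over 2-fold (63 higher, 12 lower). At an unadjusted p of 0.05 there were 1870. The WT sham and WT TAC libraries did not overlap for 1824 genes (14.6%, where chance gives 3.57%). The count was 505 with DESeq2, 723 with only the 2 groups fitted, 1146 with limma voom (560 higher, 586 lower) and 19 against a fold of 1.5. It was 109, 160 and 151 without WT sham 131, 132 and 133, 174, 210, 166 and 201 without WT TAC 134, 136, 137 and 138, and 543 without KO sham 350. Without WT TAC 135 it was 223 higher and 225 lower. Of the 20 genes with the largest changes under the fixed rule, Svep1 (3.35 ± 0.63) lost its call without WT sham 131 or 132 (adjusted p = 0.0618 and 0.0536), Col1a1 (2.17 ± 0.40) without WT sham 132 (adjusted p = 0.0541) and Igf2 (-0.86 ± 0.18) without WT sham 131 or 132 (adjusted p = 0.0738 and 0.101), all by edgeR.

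**Figure D1:**
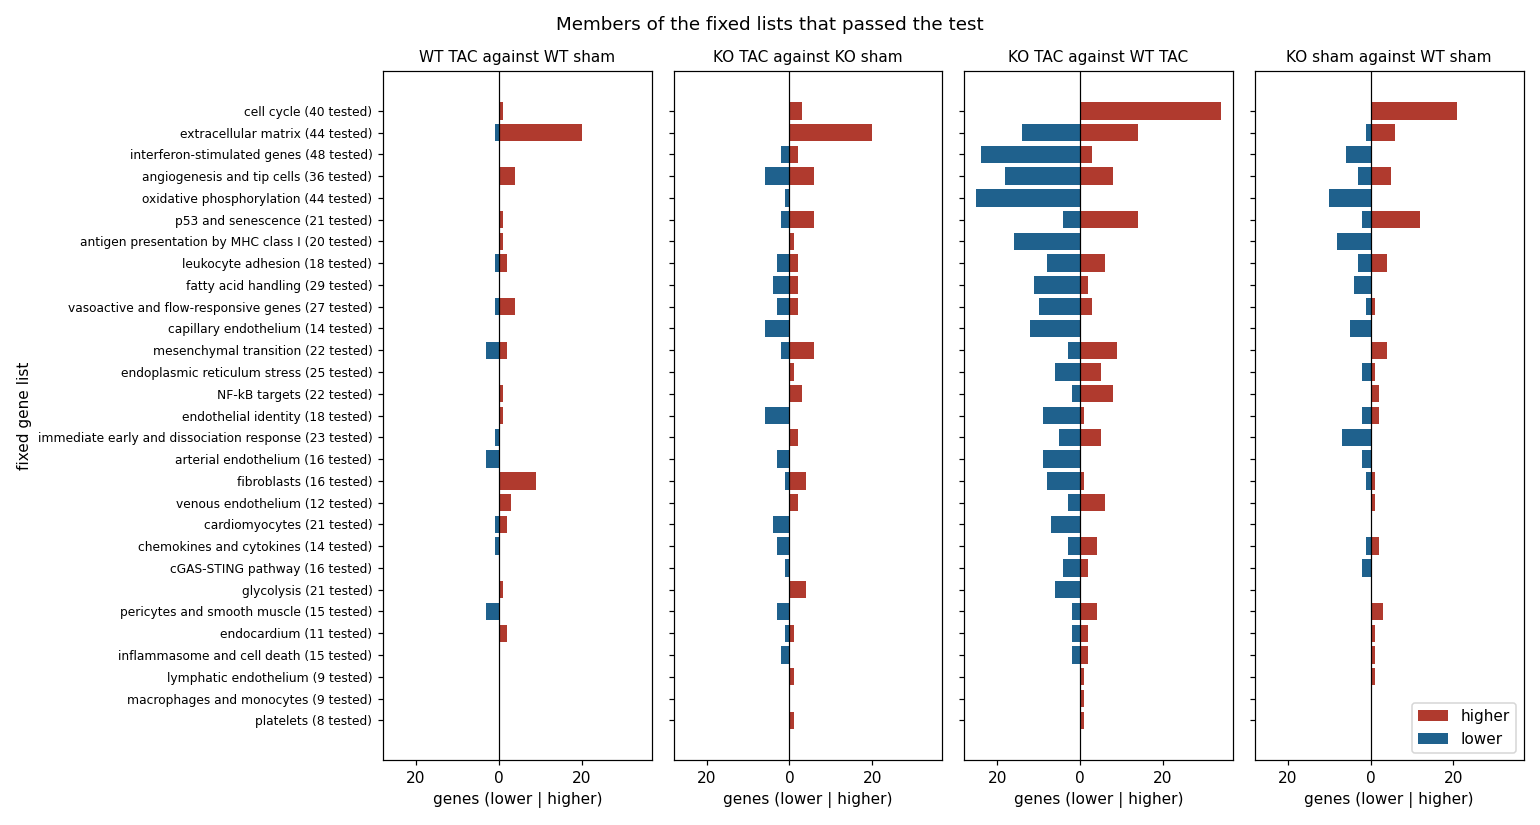
Number of genes of each fixed list that passed the test in 4 pairwise comparisons, with genes higher drawn to the right of 0 and genes lower to the left, as counts of genes. In WT TAC against WT sham 20 extracellular matrix genes were higher, and in KO TAC against WT TAC 34 cell cycle genes were higher and 25 oxidative phosphorylation genes lower.

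The second comparison, KO TAC against KO sham, asked the same question in KO mice. Here 20 of 44 matrix genes rose after TAC, 6 of 21 p53 and senescence genes rose and 2 fell, and 6 of 14 capillary and 6 of 18 endothelial identity genes fell. Col15a1 rose from 387 ± 127 to 1180 ± 334 CPM (n = 3 and 4, adjusted p = 3.24e-05 by edgeR), and Edn1 fell from 26.7 ± 4.06 to 11.0 ± 2.19 CPM (-1.29 ± 0.18, adjusted p = 0.00011 by edgeR). Car4 (chromosome 11, 84957754 to 84966054), a membrane carbonic anhydrase of capillaries, fell from 92.5 ± 10.1 to 34.6 ± 8.95 CPM, a log2 fold change of -1.42 ± 0.16 (adjusted p = 3.24e-05 by edgeR). Plvap, which forms the diaphragms of fenestrae and caveolae, rose from 3.62 ± 2.66 to 28.0 ± 8.95 CPM.

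Extracellular matrix genes rose in 20 of 44 cases and fell in none, 23 and 0 adjusted over the list alone. The median was 0.53 (camera adjusted p = 6.3e-13, and adjusted p = 0.43 with an estimated correlation). Col18a1, another basement membrane collagen, rose by 0.97 ± 0.12, the laminin-binding Nid2 (nidogen 2) by 0.90 ± 0.12 to 660 ± 130 CPM, and Mmp14, a membrane-anchored collagenase, by 1.36 ± 0.17. Adamtsl2 rose by 2.48 ± 0.55 and Bmp2, a growth factor of the TGF-beta family, by 2.50 ± 0.46. The mesenchymal transition list was not called, although 6 of its 22 members rose and 2 fell; Fn1 (fibronectin) went from 597 ± 65.2 to 957 ± 61.4 CPM and Vim (vimentin) rose by 0.67 ± 0.11, while the integrin subunit gene Itgb5 fell by 1.13 ± 0.20. Fibroblast genes summed to 387.4 ± 182 CPM in KO sham and 502.5 ± 69.5 CPM in KO TAC.

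Capillary genes fell in KO TAC, with 6 of 14 lower and none higher, 7 and 0 adjusted over the list alone, and a median of -0.35 (camera adjusted p = 6.4e-05, and adjusted p = 0.48 with an estimated correlation). Besides Car4, the fatty acid transporter Cd36 fell by 0.66 ± 0.10, from 5080 ± 291 to 3210 ± 473 CPM, and the water and glycerol channel Aqp7 by 0.92 ± 0.14. The endothelial identity list was called lower (6 of 18 lower, 7 adjusted over the list alone, none higher, median -0.19, camera adjusted p = 0.00027, and adjusted p = 0.48 with an estimated correlation). Tek, the receptor of the angiopoietins, fell by 0.62 ± 0.07 from 591 ± 59 to 384 ± 13.3 CPM and Kdr, a receptor of VEGF, by 0.42 ± 0.07. Arterial genes had 3 of 16 lower (4 adjusted over the list alone) and a camera adjusted p of 0.0029, with adjusted p = 0.48 with an estimated correlation, and the call was lost without KO sham 350 (adjusted p = 0.0842). Mecom, a transcription factor of arterial endothelium, fell by 0.53 ± 0.09 and Alpl by 1.04 ± 0.21. Cardiomyocyte genes (4 of 21 lower, 4 adjusted over the list alone, median -0.45, camera adjusted p = 0.00095, and adjusted p = 0.48 with an estimated correlation) summed to 681.8 ± 65.5 CPM in KO sham and 515.9 ± 44.4 CPM in KO TAC, and Ttn (titin) fell from 174 ± 35.3 to 74.3 ± 15.6 CPM. Pericyte and smooth muscle genes (3 of 15 lower, 5 adjusted over the list alone, median -0.60) had a camera adjusted p of 0.0018, and adjusted p = 0.48 with an estimated correlation. Their levels summed to 393.3 ± 81.8 CPM in KO sham and 281.9 ± 35.6 CPM in KO TAC.

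Of 21 p53 and senescence genes, 6 rose and 2, Cdkn1b and Sesn1, fell in KO TAC against KO sham, 11 and 2 adjusted over the list alone. The median was 0.28 (camera adjusted p = 0.0018, and adjusted p = 0.43 with an estimated correlation). Gdf15 (chromosome 8, 70629394 to 70631635), a stress-induced cytokine, rose from 27.4 ± 8.52 to 70.8 ± 16.6 CPM. Zmat3 (chromosome 3, 32334794 to 32365665), a p53 target that encodes an RNA-binding protein, rose from 103 ± 23.5 to 227 ± 25.1 CPM, and Mdm2, the ubiquitin ligase of p53, from 95.2 ± 14.9 to 150 ± 12.1 CPM. The fall of Cdkn1b lost its call without KO TAC 351 or 353 (adjusted p = 0.0545 and 0.0694 by edgeR), and that of Sesn1 kept it only without WT sham 132, KO sham 348 or KO sham 349 (highest adjusted p = 0.11, without KO TAC 351). Cell cycle genes were called higher as a list (median 0.44, 39 of 40 above 0, camera adjusted p = 0.00048, and adjusted p = 0.65 with an estimated correlation), with 3 members higher and none lower, and 0 adjusted over the list alone. Apln (apelin), a peptide of tip cells, rose from 283 ± 70.1 to 576 ± 80.1 CPM. Interferon-stimulated genes had 2 higher and 2 lower of 48 and were not called.

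Of 29 lists camera called 9 in KO TAC against KO sham, 4 higher and 5 lower, none of them with an estimated correlation (smallest adjusted p = 0.43), and fry called 5. The fibroblast list (median 0.36, adjusted p = 0.044, and adjusted p = 0.65 with an estimated correlation) lost its call with RLE scaling (adjusted p = 0.0523) and without WT sham 131, 132 or 133, WT TAC 135, KO sham 349 or 350, or KO TAC 351, 352 or 353 (adjusted p = 0.0836, 0.0601, 0.0735, 0.0611, 0.533, 0.48, 0.07, 0.0607 and 0.124). In KO TAC against KO sham 1196 genes changed, 580 higher and 616 lower, 259 of them by over 2-fold (158 higher, 101 lower), and 3133 at an unadjusted p of 0.05. Libraries of the 2 groups did not overlap for 2194 genes (17.6%, where chance gives 5.71%). The count was 374 with only the 2 groups fitted, 295 with limma voom, 41 against a fold of 1.5 and 180 with WT sham 133, KO sham 348 and KO sham 350 left out. It was 2372 without KO sham 349, 697 without KO TAC 352 and 695 without KO TAC 353. With those 3 libraries left out, the pericyte list (adjusted p = 0.361) and the endothelial identity list (adjusted p = 0.0632) lost their calls in camera.

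The third comparison, KO TAC against WT TAC, asked how KO and WT cells differed under pressure overload. In KO 34 of 40 cell cycle genes were higher, and 14 of 21 p53 genes were higher and 4 lower, while 12 of 14 capillary, 16 of 20 MHC class I, 25 of 44 oxidative phosphorylation and 24 of 48 interferon-stimulated genes (3 higher) were lower. Gdf15 was 1.75 ± 0.389 CPM in WT TAC and 70.8 ± 16.6 CPM in KO TAC, a log2 fold change of 5.33 ± 0.22 (n = 5 and 4, adjusted p = 1.4e-13 by edgeR). Apln (chromosome X, 48025146 to 48034852) rose from 80.1 ± 16.2 to 576 ± 80.1 CPM, a log2 fold change of 2.84 ± 0.14 (adjusted p = 5.31e-12 by edgeR). Car4 was 163 ± 24.9 CPM in WT TAC and 34.6 ± 8.95 CPM in KO TAC, a log2 fold change of -2.24 ± 0.15 (adjusted p = 4.12e-10 by edgeR). Ifit3 (chromosome 19, 34583529 to 34588982), an interferon-induced antiviral gene, fell from 54.1 ± 4.54 to 33.4 ± 7.63 CPM, a log2 fold change of -0.70 ± 0.13 (adjusted p = 0.000362 by edgeR).

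Cell cycle genes were higher in KO TAC for 34 of 40 tested and lower for none, 36 and 0 adjusted over the list alone. The median was 1.74 (camera adjusted p = 2.5e-17, and adjusted p = 0.21 with an estimated correlation). Mki67 (chromosome 7, 135689788 to 135716379), the gene of the proliferation marker Ki-67, rose from 26.4 ± 13 to 140 ± 25 CPM, and Cenpf, a kinetochore protein, from 7.07 ± 2.81 to 36.3 ± 3.12 CPM. Of 21 p53 and senescence genes 14 were higher and 4 lower, 14 and 6 adjusted over the list alone. The median was 0.87 (camera adjusted p = 1.7e-07, and adjusted p = 0.068 with an estimated correlation). Phlda3, an inhibitor of Akt, rose from 20.5 ± 0.454 to 108 ± 3.39 CPM and Zmat3 from 25.8 ± 2.99 to 227 ± 25.1 CPM, while Eda2r, a TNF receptor family member, rose by 2.53 ± 0.12. The members Cdkn1b, Fas and Sesn1 fell by 0.76 ± 0.07, 0.78 ± 0.17 and 0.66 ± 0.10, and Igfbp7 by 0.26 ± 0.08. Without WT TAC 134, KO TAC 352 or KO TAC 353 the call on Igfbp7 was lost (adjusted p = 0.0581, 0.0723 and 0.0884 by edgeR). Outside the lists' examples Sesn2, a stress-induced sestrin, rose from 7.55 ± 1.46 to 56.1 ± 5.08 CPM and Gtse1, a mitotic protein that binds p53, from 2.14 ± 0.484 to 33.6 ± 5.33 CPM. Zfp365 rose by 5.36 ± 0.46, the noncoding RNA Pvt1 by 4.42 ± 0.34 and Cpt1c by 3.42 ± 0.26.

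Capillary genes were lower in KO TAC for 12 of 14 tested and higher for none, 12 and 0 adjusted over the list alone. The median was -0.67 (camera adjusted p = 2.8e-08, and adjusted p = 0.21 with an estimated correlation). Cd36 fell from 6540 ± 655 to 3210 ± 473 CPM, the fatty acid binding protein gene Fabp4 from 1740 ± 235 to 893 ± 138 CPM and Tcf15, a transcription factor of heart capillaries, from 95.4 ± 11.1 to 45.7 ± 11.9 CPM. Fatty acid handling genes overlapped with these and were called lower (2 of 29 higher, 11 lower, 2 and 12 adjusted over the list alone, median -0.38, camera adjusted p = 0.0007, and adjusted p = 0.21 with an estimated correlation). Acsl1 fell by 0.77 ± 0.11. Endothelial identity genes had 1 higher and 9 lower of 18 (1 and 12 adjusted over the list alone, median -0.31, camera adjusted p = 0.00024, and adjusted p = 0.27 with an estimated correlation). Tek fell from 762 ± 28.1 to 384 ± 13.3 CPM, Tie1 from 1730 ± 80.9 to 1110 ± 48.1 CPM and Kdr from 4160 ± 249 to 3010 ± 68 CPM. Cdh5 (VE-cadherin) had a log2 fold change of 0.06 ± 0.06 (adjusted p = 0.506 by edgeR) and Pecam1, which encodes CD31, rose by 0.19 ± 0.06. Arterial genes were called lower (0 of 16 higher, 9 lower, 1 and 9 adjusted over the list alone, median -0.44, camera adjusted p = 0.0007, and adjusted p = 0.21 with an estimated correlation). The Notch ligand gene Dll4 fell from 671 ± 13.6 to 425 ± 48.3 CPM and Sox17 by 0.59 ± 0.11. Of 36 angiogenesis and tip cell genes 8 rose and 18 fell without a call for the list (camera adjusted p = 0.054): Cxcr4 fell by 1.61 ± 0.15 while Apln rose.

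MHC class I antigen presentation genes were lower in KO TAC for 16 of 20 tested and higher for none, 17 and 0 adjusted over the list alone. The median was -0.46 (camera adjusted p = 2.9e-08, and adjusted p = 0.21 with an estimated correlation). The immunoproteasome subunit genes Psmb8, Psmb9 and Psmb10 fell by 0.97 ± 0.14, 0.99 ± 0.13 and 0.80 ± 0.11. Interferon-stimulated genes were higher for 3 of 48 and lower for 24, 3 and 28 adjusted over the list alone. The median was -0.37 (camera adjusted p = 1.8e-05, and adjusted p = 0.4 with an estimated correlation). Irf7, the interferon regulatory factor that amplifies the type I response, fell from 135 ± 13.6 to 69.5 ± 9.54 CPM, Rsad2 (viperin) from 324 ± 16.4 to 183 ± 33.8 CPM and Gbp2 by 0.67 ± 0.11. The 3 higher members were Xaf1, Ifi27l2a and Eif2ak2. Of 16 cGAS-STING pathway genes 2 rose and 4 fell with no call for the list (median -0.17, mean 0.04, camera direction lower with adjusted p = 0.21). E330016A19Rik (Cgas), the DNA sensor upstream of STING, had a log2 fold change of 0.65 ± 0.27 (adjusted p = 0.074 by edgeR), the kinase gene Tbk1 0.07 ± 0.08 (adjusted p = 0.544) and Irf3 -0.17 ± 0.11 (adjusted p = 0.265). The adhesion molecule gene Icam1 rose from 94.7 ± 6.72 to 150 ± 37.7 CPM and the monocyte chemokine gene Ccl2 from 1.28 ± 0.615 to 6.15 ± 3.5 CPM, while leukocyte adhesion genes as a list had 6 higher and 8 lower of 18 (median 0.00, camera direction lower with adjusted p = 0.27).

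Oxidative phosphorylation genes were lower in KO TAC for 25 of 44 tested and higher for none, 27 and 0 adjusted over the list alone. The median was -0.34 (camera adjusted p = 1.3e-07, and adjusted p = 0.21 with an estimated correlation). Cox4i1, a subunit of cytochrome c oxidase, fell from 109 ± 9.88 to 69.1 ± 5.65 CPM and Uqcrh by 0.91 ± 0.14. Short genes in general were lower in KO TAC: the trend of log2 fold change on gene length gave -0.30 at 748.5 exon bases, the median length of this list, against 2906 bases for all genes tested. The part of gene length in the other lists called lower in KO, such as MHC class I and interferon-stimulated genes, was not examined after either surgery. Extracellular matrix genes had 14 higher and 14 lower of 44, with no call (median -0.06, mean -0.13, camera direction higher with adjusted p = 0.71). Nid2 rose by 1.26 ± 0.10 and Col18a1 by 0.99 ± 0.10, while Dcn (decorin), a proteoglycan of fibroblasts, fell from 83.7 ± 20.9 to 36.0 ± 10.3 CPM. Fibroblast markers were called lower (1 of 16 higher, 8 lower, 1 and 9 adjusted over the list alone, median -1.01, camera adjusted p = 0.0073, and adjusted p = 0.4 with an estimated correlation), with Pdgfra falling from 26.5 ± 4.56 to 8.44 ± 0.715 CPM. Cardiomyocyte genes were lower for 7 of 21 (9 adjusted over the list alone, median -0.69, camera adjusted p = 0.001, and adjusted p = 0.28 with an estimated correlation). Mesenchymal transition genes had 9 higher and 3 lower of 22, the same adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.013, and adjusted p = 0.21 with an estimated correlation). Fn1 rose by 1.18 ± 0.10 and Smad3 by 1.38 ± 0.21. Of 27 vasoactive genes 3 rose and 10 fell, 3 and 11 adjusted over the list alone, median -0.23 (camera adjusted p = 0.023, and adjusted p = 0.21 with an estimated correlation), with Thbd (thrombomodulin) falling from 1320 ± 108 to 680 ± 49.5 CPM and Ednrb by 1.17 ± 0.12. Edn1 had a log2 fold change of -0.08 ± 0.17 (adjusted p = 0.75 by edgeR). Cyp1a1 fell from 10.0 ± 4.62 to 0.266 ± 0.159 CPM, Klra9 from 40.6 ± 8.55 to 5.83 ± 2.57 CPM and the water channel gene Aqp1 from 4310 ± 526 to 1260 ± 471 CPM.

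In KO TAC against WT TAC camera called 13 of 29 lists, 3 higher and 10 lower, none with an estimated correlation (smallest adjusted p = 0.068), and fry called 18. Of the genes tested 3715 changed, 1846 higher and 1869 lower, 703 of them by over 2-fold (538 higher, 165 lower), and 4982 at an unadjusted p of 0.05. Libraries of the 2 groups did not overlap for 3823 genes (30.7%, where chance gives 1.59%). The count was 1763 with the mean level of the cardiomyocyte list as a covariate and 480 (344 higher, 136 lower) against a fold of 1.5. Under that covariate the fibroblast list (adjusted p = 0.332), the mesenchymal transition list (adjusted p = 0.0639) and the cardiomyocyte list itself (adjusted p = 0.954, direction turned) were not called in camera. The cardiomyocyte list itself differed between the groups, with sums of 481.9 to 581.1 CPM in KO TAC and 598.1 to 683.6 CPM in WT TAC. The covariate may therefore take up part of the genotype difference, and the lost calls cannot be ascribed to cardiomyocyte RNA. All KO mice carried Cre and all WT mice did not, so the effect of the deletion and that of the recombinase were measured together. The labels do not say which mice received tamoxifen, which CreERT2 needs, so an effect of the drug is not separated either.

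**Figure D2:**
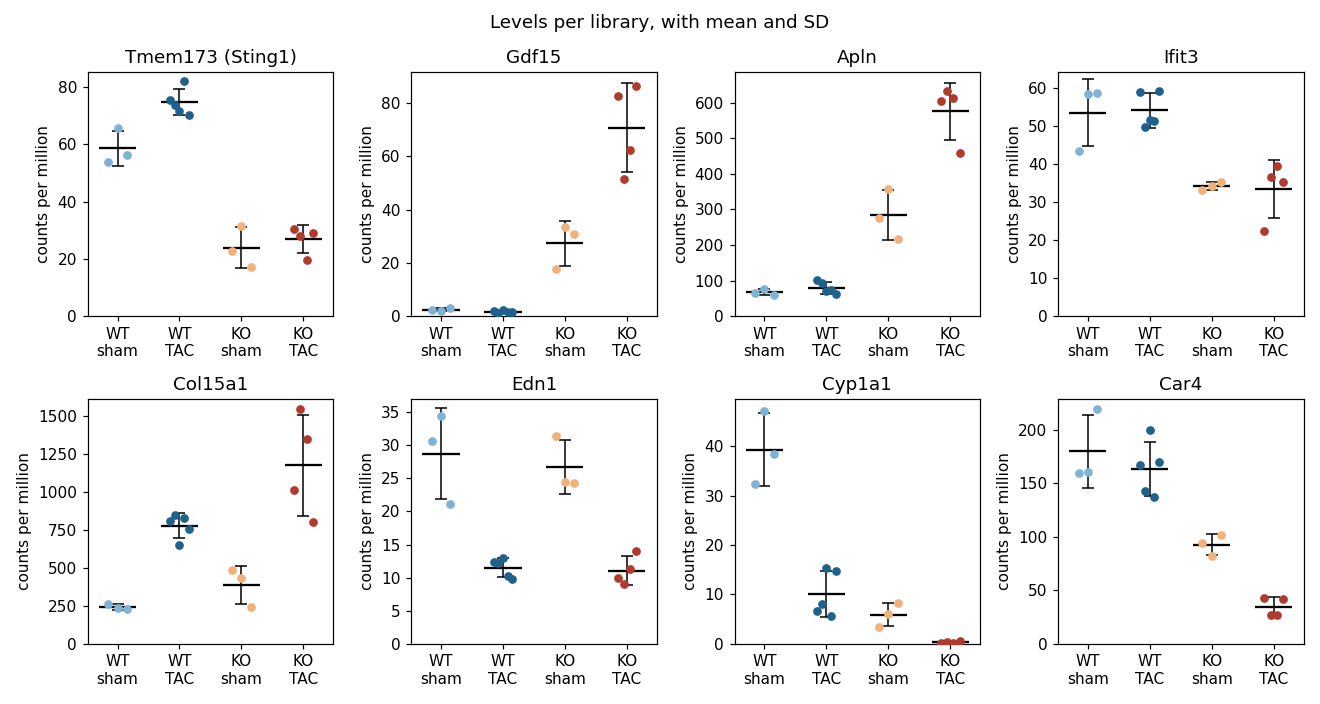
CPM (vertical, linear axes from 0, 1 panel per gene) of 8 genes in each of the 15 libraries, grouped along the horizontal axis as WT sham, WT TAC, KO sham and KO TAC, with each point a library, each line the mean and each error bar 1 SD. Gdf15 lay at 1.75 ± 0.389 CPM in WT TAC and 70.8 ± 16.6 CPM in KO TAC, while Edn1 was lower after TAC than after sham in both genotypes.

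The fourth comparison, KO sham against WT sham, asked which of these differences were present without pressure overload. In KO sham 21 of 40 cell cycle and 12 of 21 p53 genes (2 lower) were higher, and 8 of 20 MHC class I, 10 of 44 oxidative phosphorylation and 6 of 48 interferon-stimulated genes were lower. Gdf15 was 2.49 ± 0.508 CPM in WT sham and 27.4 ± 8.52 CPM in KO sham, a log2 fold change of 3.58 ± 0.30 (n = 3 and 3, adjusted p = 1.45e-07 by edgeR). Apln rose from 68.1 ± 8.82 to 283 ± 70.1 CPM, a log2 fold change of 2.03 ± 0.18 (adjusted p = 3.63e-07 by edgeR). Isg15, a ubiquitin-like interferon-induced protein, fell from 38.5 ± 4.27 to 18.6 ± 5.19 CPM, a log2 fold change of -1.04 ± 0.19 (adjusted p = 0.00168 by edgeR). Fabp4 fell from 2190 ± 466 to 875 ± 85.2 CPM, a log2 fold change of -1.32 ± 0.14 (adjusted p = 4.18e-06 by edgeR).

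Of 40 cell cycle genes 21 were higher in KO sham and none lower, 28 and 1 adjusted over the list alone. The median was 1.45 (camera adjusted p = 2.5e-13, and adjusted p = 0.22 with an estimated correlation). Prc1, which organises the spindle midzone, rose by 2.16 ± 0.34 and the kinase gene Cdk1 by 1.98 ± 0.32. P53 and senescence genes had 12 higher and 2 lower of 21, 12 and 4 adjusted over the list alone. The median was 0.65 (camera adjusted p = 2.9e-07, and adjusted p = 0.069 with an estimated correlation). Zmat3 rose from 21.3 ± 3.88 to 103 ± 23.5 CPM and Phlda3 from 19.6 ± 0.902 to 69.8 ± 7.4 CPM. Mesenchymal transition genes had 4 higher and none lower of 22, 6 and 0 adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.0036, and adjusted p = 0.22 with an estimated correlation), and Fn1 rose by 0.61 ± 0.13. Sulf2, an extracellular sulfatase, rose from 2.48 ± 0.993 to 19.4 ± 4.96 CPM and Ltc4s, the leukotriene C synthase, from 2.19 ± 0.653 to 20.2 ± 1.67 CPM.

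MHC class I genes were lower in KO sham for 8 of 20, 13 adjusted over the list alone, and higher for none. The median was -0.34 (camera adjusted p = 1.7e-05, and adjusted p = 0.53 with an estimated correlation). Psmb8 fell from 88.8 ± 8.11 to 49.3 ± 6.88 CPM. Of 48 interferon-stimulated genes 6 were lower and none higher, 9 and 0 adjusted over the list alone. The median was -0.17 (camera adjusted p = 0.0054, and adjusted p = 0.53 with an estimated correlation). Bst2 (tetherin) fell by 0.90 ± 0.16, and the call on the interferon list was lost without WT sham 132 (adjusted p = 0.0818) or KO sham 349 (adjusted p = 0.0674). Ifit1 fell by 0.59 ± 0.17, which was lost without WT sham 132 or KO sham 350 (adjusted p = 0.242 and 0.0641 by edgeR). Capillary genes were lower for 5 of 14 (5 adjusted over the list alone, median -0.33, camera adjusted p = 0.0045, and adjusted p = 0.53 with an estimated correlation). Without KO sham 349 that call was lost (adjusted p = 0.0665). Tcf15 fell by 1.29 ± 0.17 and Car4 by 0.93 ± 0.17. Arterial genes were also called lower (2 of 16, 4 adjusted over the list alone, median -0.18, camera adjusted p = 0.034, and adjusted p = 0.53 with an estimated correlation). Without WT sham 132, KO sham 348 or KO sham 349 that call was lost (adjusted p = 0.0818, 0.194 and 0.23). Rbp7 fell by 1.05 ± 0.16. Venous genes were called higher, with 1 of 12 higher (5 adjusted over the list alone, median 0.39, camera adjusted p = 0.013, and adjusted p = 0.22 with an estimated correlation), and lost the call without KO sham 349 (adjusted p = 0.0665). Immediate early genes were lower for 7 of 23 and higher for none, the same adjusted over the list alone. The median was -0.44 (camera adjusted p = 0.0022, and adjusted p = 0.53 with an estimated correlation). Ier2 fell from 309 ± 63.6 to 165 ± 13 CPM, and the call on that list was lost without WT sham 133 (adjusted p = 0.12).

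Oxidative phosphorylation genes were lower in KO sham for 10 of 44, 16 adjusted over the list alone, and higher for none. The median was -0.36 (camera adjusted p = 2.9e-07, and adjusted p = 0.23 with an estimated correlation). Cox4i1 fell from 114 ± 9.55 to 58.5 ± 14.3 CPM, and Atp5j by 1.24 ± 0.21. Here too the trend on gene length gave -0.31 at the median length of the list. Pericyte genes were called higher (3 of 15 higher, 3 adjusted over the list alone, median 0.30, camera adjusted p = 0.0092, and adjusted p = 0.53 with an estimated correlation) and lost the call without KO sham 350 (adjusted p = 0.132). Their sum was 295.1 ± 24.5 CPM in WT sham and 393.3 ± 81.8 CPM in KO sham. Among the genes with the largest decreases, the small nucleolar RNA Snord22 fell by 1.70 ± 0.23, the ribosomal protein gene Rpl27 by 1.53 ± 0.23, and Snhg8 went from 18.1 ± 4.62 to 6.15 ± 1.56 CPM. Rprl3, a gene of 237 bases (chromosome 8, 3803125 to 3803361), held 164, 245 and 197 CPM in KO sham 348, 349 and 350 and 0 of 26156635 counts in the 3 WT sham libraries, so that its mean of 202 CPM in KO sham was 1710 times the floor of 3 pooled counts in WT sham, 0.118 CPM (adjusted p = 3.48e-14 by edgeR). It had 2 counts over the KO TAC and 1 over the WT TAC libraries. The level of Rprl3 thus followed neither genotype nor surgery alone. Whether the difference lies in expression, in the assignment of reads or in the libraries was not tested.

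Camera called 11 of 29 lists in KO sham against WT sham, 5 higher and 6 lower, none with an estimated correlation (smallest adjusted p = 0.069), and fry called 7. Of the genes tested 1148 changed, 570 higher and 578 lower, 282 of them by over 2-fold (194 higher, 88 lower), and 2974 at an unadjusted p of 0.05. The 3 libraries of each group did not overlap for 2794 genes (22.4%, where chance gives 10%). The count was 289 with only the 2 groups fitted, 463 with limma voom, 77 against a fold of 1.5 and 292 with WT sham 133, KO sham 348 and KO sham 350 left out, where the pericyte (adjusted p = 0.77) and mesenchymal transition (adjusted p = 0.183) lists were no longer called. It was 505 without WT sham 132, 599 without WT sham 133, 742 without KO sham 348 and 2014 without KO sham 349. Of genes higher in KO, 441 were called in both the sham and the TAC comparison, where 84.4 would be shared by independent calls, and 407 of those lower, where 86.6 would be (both comparisons use different libraries). The log2 fold changes of KO against WT in sham and in TAC had a Pearson correlation of 0.507 across genes, which are not independent replicates.

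The last comparison asked whether the response to TAC differed between the genotypes, as the difference of the 2 TAC effects in the same edgeR fit. The fall in Edn1 differed by 0.08 ± 0.25 (adjusted p = 0.918), while 4 of 18 endothelial identity, 2 of 14 capillary and 5 of 36 angiogenesis genes had lower fold changes in KO. Efna1 (chromosome 3, 89271730 to 89280951), an ephrin ligand of endothelium, went from 186 ± 15.2 to 213 ± 22.7 CPM in WT and from 143 ± 20.4 to 75.6 ± 9.75 CPM in KO, a difference of -1.13 ± 0.16 (n = 3, 5, 3 and 4, adjusted p = 0.00385 by edgeR). Jam2 (chromosome 16, 84774123 to 84826375), a junctional adhesion molecule, went from 1070 ± 85.9 to 1210 ± 67.4 CPM in WT and from 840 ± 96.8 to 523 ± 43.6 CPM in KO, a difference of -0.85 ± 0.12 (adjusted p = 0.00385 by edgeR). Car4 differed by -1.31 ± 0.22 (adjusted p = 0.0117 by edgeR), and Mdm2 by 0.80 ± 0.14 in the other direction (adjusted p = 0.0138 by edgeR).

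Of the 18 endothelial identity genes 4 had a lower TAC response in KO and none a higher one, 9 and 0 adjusted over the list alone. The median was -0.29 (camera adjusted p = 4e-07, and adjusted p = 0.32 with an estimated correlation). Tek differed by -0.56 ± 0.10. Capillary genes were called lower (2 of 14, 5 adjusted over the list alone, median -0.39, camera adjusted p = 0.00047, and adjusted p = 0.49 with an estimated correlation). Angiogenesis and tip cell genes had 5 lower of 36 and none higher, 10 and 2 adjusted over the list alone. The median was -0.20 (camera adjusted p = 0.003, and adjusted p = 0.2 with an estimated correlation). Cxcr4 differed by -1.28 ± 0.24, and without WT sham 133 that call was lost (adjusted p = 0.052). Trp53i11 differed by -0.62 ± 0.12, and without WT sham 131 or 133 or KO TAC 352 that call was lost (adjusted p = 0.0961, 0.0538 and 0.0525). Leukocyte adhesion genes had 1 lower of 18, 4 adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.00088, and adjusted p = 0.32 with an estimated correlation). Fcgrt, the neonatal Fc receptor, differed by -0.82 ± 0.12, the slingshot phosphatase gene Ssh2 by -0.75 ± 0.11, Fxyd6 by -0.94 ± 0.15, Sema6a by -0.67 ± 0.11, the oxygenase gene Fmo1 by -0.66 ± 0.11 and Klra9 by -2.07 ± 0.36. Fibroblast genes had 0 of 16 past the edgeR test (9 at an unadjusted p under 0.05, 0 in DESeq2 and in limma voom), 5 lower adjusted over the list alone. The median was -1.16 (camera adjusted p = 0.003, and adjusted p = 0.54 with an estimated correlation). Without KO sham 348 the call was lost (adjusted p = 0.194), and so it was under the cardiomyocyte covariate (adjusted p = 0.129). P53 genes had 3 higher of 21, 7 higher and 1 lower adjusted over the list alone. The median was 0.35 (camera adjusted p = 0.0054, and adjusted p = 0.32 with an estimated correlation). Without KO sham 348 the call was lost (adjusted p = 0.0694), and so it was with the 3 libraries left out (adjusted p = 0.234). Of the 48 interferon-stimulated genes 0 passed in edgeR, 11 had an unadjusted p under 0.05, DESeq2 called 2 and limma voom 0: Isg15 had a difference of 0.59 ± 0.24 (adjusted p = 0.259 by edgeR) and Ifit3 -0.08 ± 0.21 (adjusted p = 0.901).

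Of 29 lists 11 were called, 3 higher and 8 lower in KO, none with an estimated correlation (smallest adjusted p = 0.2), and fry called 3. In all, 86 genes differed in their response to TAC, 25 with a higher and 61 with a lower fold change in KO, 19 of them by over 2-fold (7 higher, 12 lower), and 1819 at an unadjusted p of 0.05. A fit without WT sham 133, KO sham 348 and KO sham 350 leaves 1 KO sham library, so it cannot decide which of these genes differ. The count was 314 with DESeq2, 174 with no low-count filter, 56 with the cardiomyocyte covariate and 0 against a fold of 1.5 (335 at an unadjusted p under 0.05). It was 27, 46 and 25 without WT sham 131, 132 and 133, 43, 168 (81 higher, 87 lower), 31, 35 and 45 without WT TAC 134 to 138, 764 (405 higher, 359 lower) without KO sham 349 and 48, 36 and 37 without KO TAC 351, 352 and 353.

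Genes that rose after TAC were shared between the genotypes for 88 of the 200 called in WT, where 9.3 would be shared by independent calls (Fisher's exact test p = 1.69e-64), and 172 of the 200 lay above 0 in KO. Of the 123 that fell in WT 45 also fell in KO, where 6.08 would be shared (p = 8.43e-28, Fisher's exact test). Genes are not independent replicates and both sets of calls come from the same fit, so the Fisher p-values do not measure the spread between mice. Col15a1, Postn, Cilp, Cd34, Edn1 and Cxcl12 were among the genes that changed the same way in both. Across all genes tested the 2 TAC responses, which share no library, had a Pearson correlation of 0.288 and a Spearman correlation of 0.225, with a covariance of 0.0758. Over 50 random splits of the libraries the covariance lay between -0.0399 and 0.0194. The correlation was 0.16 to 0.307 when single libraries were left out. The KO effect after TAC and the WT response to TAC, which share the WT TAC libraries, had a correlation of -0.0864 and a covariance of -0.0206, where unchanged groups gave -0.332 and -0.0271 in simulation. With the WT TAC libraries split between the 2 comparisons, the correlation was -0.00641 and the covariance -0.00125, against -0.00438 and -0.000486 in simulation.

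**Figure D3:**
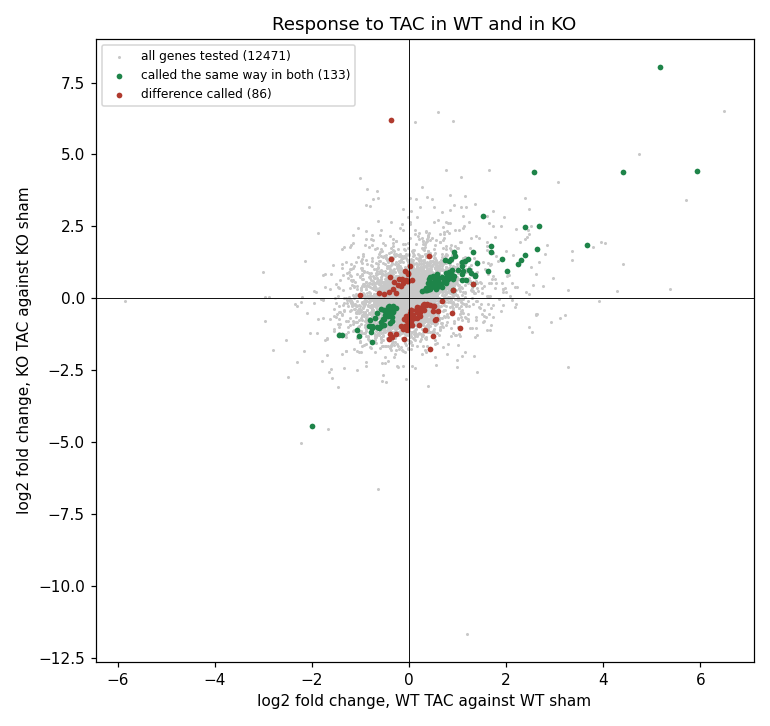
Log2 fold change of TAC against sham in KO (vertical) against that in WT (horizontal) for the 12471 genes tested, with the genes called in both comparisons and those called in the test of the difference drawn in colour. The 88 genes that rose and 45 that fell in both lie in opposite corners, and the correlation over all genes was 0.288.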

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

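In this part only the 3 tests of the p53 pattern were chosen after its result was seen. In WT TAC and KO TAC, the groups with at least 4 libraries, Dixon's test at the 95% level set a library apart from the rest of its group in 19 of 288 sets of values examined, and chance flags about 1 in 20 groups. Within WT TAC these were Col4a1 at 6898 CPM in library 134, Fosb at 236.1, Neat1 at 521.7 and Ldha at 248.5 CPM in 135, Mmp14 at 25.34 and Acsl1 at 57.82 CPM in 136, and Ccl2 at 2.336 CPM in 138. Within KO TAC they were Kcnq1ot1 at 305.7 and Xaf1 at 46.09 CPM in library 351, and E330016A19Rik (Cgas) at 14.46 CPM, Prc1 at 47.56 CPM, the summed neutrophil genes at 2.705 CPM and 13 genes at 0 where at least 10 counts were expected in 352. Library KO TAC 354 stood apart for Apln at 457.6, Phlda3 at 102.8, Psmb8 at 72.44 and Icam1 at 206.5 CPM. Rprl3 had 0.06686 CPM in WT TAC 135 and 0.1595 CPM in KO TAC 351, and 0 in the other TAC libraries.

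The test of the difference between the TAC responses of KO and WT called 13 genes the report names. These calls belong to a count that was not stable. Against a fold of 1.5 the 86 genes called became 0. With single libraries left out they ranged from 25 without WT sham 133 to 764 without KO sham 349. The differences in log2 fold change, KO minus WT, were -1.13 for Efna1, -0.85 for Jam2, -1.31 for Car4, -0.56 for Tek, -1.28 for Cxcr4, -0.62 for Trp53i11, -0.82 for Fcgrt, -0.75 for Ssh2, -0.94 for Fxyd6, -0.67 for Sema6a, -0.66 for Fmo1 and -2.07 for Klra9, and 0.80 for Mdm2. Single libraries ended the calls on Cxcr4 (adjusted p = 0.052 without WT sham 133) and Trp53i11 (adjusted p = 0.0961, 0.0538 and 0.0525 without WT sham 131, WT sham 133 and KO TAC 352). Of 100 random splits by genotype within surgery 3, the real one included, gave at least the 86 genes of the real grouping, and the highest other gave 346. These splits do not keep the difference between the genotypes, with 3715 genes called after TAC and 1148 after sham, so they cannot tell whether chance gives 86 genes. The structure behind the 346 includes that difference, because this split exchanged the genotype of 8 of the 9 TAC and 2 of the 6 sham libraries.

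The same test called 11 lists by camera, and none of them with an estimated correlation. The median differences were -0.29 for endothelial identity, -0.39 for capillary, -0.20 for angiogenesis and tip cell and -0.28 for leukocyte adhesion genes, 4 lists called without each of the 15 libraries. For fibroblast genes (-1.16), p53 genes (0.35) and cardiomyocyte genes (-0.58) the call ended without KO sham 348 (adjusted p = 0.194, 0.0694 and 0.0566). Vasoactive genes (-0.18) lost it without WT sham 131, WT TAC 138, KO sham 349, KO sham 350 or KO TAC 352 (adjusted p = 0.061, 0.0615, 0.055, 0.0695 and 0.0649), and immediate early genes (0.22) without WT sham 133, KO sham 348, KO sham 349 or KO TAC 354 (adjusted p = 0.386, 0.127, 0.103 and 0.0587). Cell cycle genes (0.14) lost it without WT sham 131, WT TAC 136, WT TAC 138, KO sham 350 or KO TAC 352 (adjusted p = 0.149, 0.148, 0.141, 0.201 and 0.215). MHC class I genes (-0.12, camera adjusted p = 0.043) lost it without WT sham 131 or 133, WT TAC 134 or 138, KO sham 349 or 350, or KO TAC 351, 352 or 353 (adjusted p = 0.199, 0.0724, 0.0867, 0.123, 0.055, 0.463, 0.211, 0.0557 and 0.134).

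The p53 list, with Gdf15, Zmat3 and Phlda3, was called higher in KO than in WT by camera after both surgeries. With an estimated correlation camera did not call it (adjusted p = 0.068 after TAC and 0.069 after sham). The low-complexity KO sham libraries are not part of the comparison after TAC, where a fit of the TAC libraries alone called 14 of 21 members higher and 4 lower. This argues against these libraries as the cause after TAC. The sham comparison without KO sham 348, KO sham 350 and WT sham 133 left 1 KO sham library, with a median log2 fold change of 0.705 over the members. With 1 library it cannot decide the question after sham. Stress during dissociation stays open: the immediate early list was lower in KO sham (camera adjusted p = 0.0022, adjusted p = 0.53 with an estimated correlation, and adjusted p = 0.12 without WT sham 133), where stress would raise it, and had 5 genes higher and 5 lower after TAC. An effect of the Sting1 deletion cannot be told apart from an effect of Cre recombinase or of the separate KO cohort, because 0 libraries with Cre and intact Sting1 are in the series. The pattern may therefore reflect the deletion, Cre, the cohort or stress during dissociation, and after sham also the low-complexity libraries.

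The extracellular matrix list rose after TAC together with fibroblast markers, in cells sorted for CD31. For the 10 basement membrane genes examined, such as Col4a1 and Col15a1, the summed rise in WT TAC was 13.8 times that of the 18 fibroblast genes, 5470 against 398 CPM. In single WT TAC libraries it was 8.04 to 18.6 times. This ratio passed the bound fixed beforehand against RNA of fibroblasts. Fibroblast RNA alone would have to hold these genes at 13.8 times the level of the markers, which was not measured. As a sum led by abundant genes, the ratio cannot decide the source of each gene. The 10 fibroblast markers tested outside the matrix list had a median log2 fold change of 0.735, with 9 above 0 and 4 called higher. This met the bound fixed beforehand for RNA of fibroblasts. It cannot decide the source, because these are among the markers whose rise was to be explained. RNA of fibroblasts remains a candidate source for them. Of the fibroblast genes 6 are also in the matrix list. The most abundant of the markers outside it was Gsn, with 145 ± 82.9 CPM in WT sham and 288 ± 77 CPM in WT TAC. An effect of pressure overload on the endothelial cells stays open for the basement membrane genes and for the markers.

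Camera called oxidative phosphorylation genes lower in KO after both surgeries, though not with an estimated correlation. Of 44 genes 25 passed edgeR as lower after TAC and 10 after sham. The genes are short, with a median of 748.5 exon bases against 2906 for all genes tested. The trend of log2 fold change on gene length gave -0.303 at that length after TAC, close to the list's median of -0.337. With the trend removed the median was -0.113 ± 0.045 (bootstrap SE, 44 genes) after TAC, where the test left the question open, and -0.1 after sham. Gene length bias and a lower expression of these genes in KO therefore cannot be told apart here, because the trend and the list cover the same short genes. Some of the difference may come with length alone.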

How the results depend on the processing

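Here only the fit without WT sham 133, KO sham 348 and KO sham 350 was chosen after seeing the data. With 1 KO sham library left, that fit takes its spread from the other groups, and its counts cannot decide stability. A result counts as reversed only where it or the alternative was called. Of 154 gene results named and called, 109 were called under all alternatives other than the test against a fold of 1.5, which called 74, and 144 without each library; DESeq2, RLE factors and the 5 CPM filter called all 154, the covariate 141 and the 3-library fit 126. These counts do not measure stability in general, since genes whose call did not rest on 1 library were preferred for naming. Genes changed in WT TAC against WT sham, 323, became 505 with DESeq2, 723 with only the groups compared, 1146 with limma voom and 19 against a fold of 1.5, and ranged from 109 to 543 with single libraries left out. In KO TAC against KO sham, 1196 became 374 with only the groups compared, 295 with voom, 41 against a fold of 1.5 and 180 in the 3-library fit (695 to 2372). In KO TAC against WT TAC, 3715 became 1763 with the cardiomyocyte covariate and 480 against a fold of 1.5 (2868 to 4539). In KO sham against WT sham, 1148 became 289 with only the groups compared, 463 with voom, 77 against a fold of 1.5 and 292 in the 3-library fit (505 to 2014). For the difference of the TAC effects, 86 became 314 with DESeq2, 174 with no filter, 56 with the covariate, 0 against a fold of 1.5 and 5 in the 3-library fit (25 to 764). A fold threshold is stricter by construction; for the others the cause was not tested.

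Lists called in the 5 comparisons, in the order above, were 3, 0, 0, 0 and 0 with an estimated correlation against 9, 9, 13, 11 and 11; fry called 5 in KO TAC against KO sham, 7 in KO sham against WT sham and 3 for the difference. With single libraries left out they numbered 6 to 10, 8 to 11, 13 to 14, 8 to 14 and 7 to 14. The cardiomyocyte list in KO TAC against WT TAC reversed its direction (adjusted p = 0.954) with its own mean as the covariate, by construction. Sting1 stayed called under all alternatives, at -1.54 to -1.35 after TAC and -1.54 to -1.11 after sham without single libraries. The correlation of the TAC responses was 0.16 to 0.307, and that of the KO effect with the WT response -0.0733 to 0.0306. The sex covariate was not run. No paired analysis was possible because mouse numbers pair no samples. Depth limits genes under about 2.2 CPM in WT sham 133, the value of 3 counts there, and 1-library differences in the sham groups of 3.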

Other observations

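Further gene groups were examined in KO TAC against WT TAC, none called by camera as a list. Of 22 NF-kB targets 8 rose and 2 fell, 9 and 3 adjusted over the list alone (camera adjusted p = 0.21): Plau, the urokinase gene, rose from 14.9 ± 1.38 to 37.7 ± 4.24 CPM and the apoptosis regulator Cflar by 0.48 ± 0.08, while the receptor gene Tnfrsf1b fell by 0.70 ± 0.12. Of 12 venous genes 6 rose and 3 fell, 7 and 3 adjusted over the list alone (camera adjusted p = 0.5); Sele (E-selectin) rose from 1.54 ± 0.451 to 6.24 ± 2.27 CPM and Mgp fell by 0.75 ± 0.17. Glycolysis genes had 0 of 21 higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.31), with Ldha falling by 0.37 ± 0.08. Of 25 endoplasmic reticulum stress genes 5 rose and 6 fell, 5 and 7 adjusted over the list alone (camera adjusted p = 0.2), with Herpud1 falling by 0.64 ± 0.10 and Sesn2 rising. In the lymphatic list Sema3d, a guidance molecule, rose from 14.3 ± 2.74 to 47.0 ± 16.9 CPM and was the only one of 9 called (camera adjusted p = 0.99).

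Marker genes of other cell types summed to less than the 22490 to 26230 CPM of the 18 endothelial identity genes. The lists differ in size and in the levels of their genes, so the sums are no shares of RNA or of cells. The largest sums, as group means, were 515.9 to 695.8 CPM for cardiomyocyte and 371.9 to 769.5 CPM for fibroblast genes. Pericyte and smooth muscle genes followed with 266.5 to 393.3 CPM. Macrophage and monocyte genes summed to 29.48 ± 6.55, 26.09 ± 3.49, 24.04 ± 4.66 and 24.28 ± 4.3 CPM in WT sham, WT TAC, KO sham and KO TAC, and lymphocyte genes to 1.822 to 3.324 CPM as group means. Erythroid genes summed to 80.39 ± 24.7, 55.65 ± 15.4, 45.66 ± 4.45 and 27.79 ± 5.91 CPM, and platelet genes to 46.18 ± 11.3, 46.52 ± 9.81, 39.6 ± 9.5 and 52.97 ± 12.6 CPM. The mesothelial list summed to 134.5 ± 19.3 CPM in KO TAC and 81.26 ± 8.79 CPM in WT TAC, but only 1 of its genes, Wt1, was tested. Wt1 made up nearly all of the sum and rose from 81.03 ± 8.86 to 133.9 ± 19.2 CPM (0.72 ± 0.09, adjusted p = 5.6e-06 by edgeR). With the list's other genes almost absent, the sum is no measure of mesothelial RNA, and the source of Wt1 was not tested.

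Other groupings of the same libraries were tested for the 4 pairwise comparisons. For WT TAC against WT sham the real count of 323 was reached by 1 of 56 splits, the real one (highest other 12). For KO TAC against KO sham 1196 was reached by 1 of 35 (highest other 358), and for KO TAC against WT TAC 3715 by 1 of 100 (highest other 1179). In these 3 the share of splits was under 0.05, with no adjustment over the comparisons. Such splits do not address differences tied to cohort or library quality. For KO sham against WT sham 3 against 3 libraries make 10 splits, too few for a share under 0.05; the real count was 1148 and the highest other 3.

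Cyp1a1, the classic target of the aryl hydrocarbon receptor, fell after TAC in both genotypes and was lower in KO than in WT after both surgeries, from 39.4 ± 7.45 CPM in WT sham to 0.266 ± 0.159 CPM in KO TAC. One hypothesis is a lower response of this receptor in KO endothelium. The test, fixed before its result was seen, took the receptor's other targets: Cyp1b1, Tiparp and Nqo1, the 3 that could be tested, had a median log2 fold change of -0.26 in KO TAC against WT TAC, between the bounds of -0.5 and -0.1 set for it, and none was called, so 3 genes leave the hypothesis open. The TAC effect on Cyp1a1 itself differed between genotypes by -2.45 ± 0.66 (adjusted p = 0.085 by edgeR).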
